A study of Gossypium hirsutum with 24 samples.

How the data were processed

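RNA of control and drought plants was hybridised to Affymetrix cotton arrays, 3 per group at 0, 5, 10 and 20 dpa, and the values used were those deposited by the authors in 1 table of 24132 probe sets by 24 arrays. Per the submitters' processing notes the deposited values were made by RMA, whose version is not given in the sources used here; RMA gives log2 values, so the unit is taken as log2. In the deposited log2 values the median over the 6 arrays of a stage was 0 for every probe set, to within 5e-07, in each of the 4 stages. The authors therefore centred each probe set within its stage, a step that is not stated, and which arrays were normalised together is not given in the sources used here. Absolute signals and array images were not available.

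The centring keeps differences between drought and control within a stage, and differences of these effects between stages. It removes the level of each probe set and its change between stages in control plants. Comparisons between control stages, a filter on dim probe sets, a floor on low signals and a choice of the brightest probe set per gene had been planned before the data were examined and could not be computed. The probe set standing for a gene was therefore chosen without regard to values, by sense design first, then by the suffix least prone to cross-hybridise, then by its ID. Of the genes with 2 or more called probe sets, 18 of 43 at 0 dpa, 7 of 75 at 5 dpa, 5 of 82 at 10 dpa and 24 of 76 at 20 dpa had probe sets called in opposite directions, so a value belongs to the probe set chosen. A probe set with a suffix _s_at or _x_at can bind related transcripts, which holds for 25 of the 50 genes named by the rule below, G9, SusA1 and NAC4 among them; 4 named genes, AOX1, pod10, GEPH and CesA1, were read by probe sets of antisense design.

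The 159 Affymetrix control probe sets were left out of the tests, which leaves 23973. limma 3.58.1 in R 4.3.3 fitted the means of the 8 groups to all 24 arrays (16 residual degrees of freedom, lmFit and eBayes). Contrasts were drought minus control at each stage, their mean, and the differences between consecutive stages. P-values are two-sided and adjusted by Benjamini-Hochberg over the probe sets of a contrast, and a probe set was called at an adjusted p under 0.05. The drought effect across stages was compared by overlaps of calls, with one-sided Fisher's exact tests (the hypergeometric tail), and by correlations across probe sets over 6 pairs of stages. Other splits of the arrays into groups were fitted in the same way, all 10 for a stage and 100 drawn with a fixed seed for the other contrasts.

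The annotation gave genes for 743 probe sets, 697 with 1 gene and 46 with several, and all 520 genes with such a probe set were found in the RefSeq table of the assembly Gossypium_hirsutum_v2.1. That table gives no descriptions, so gene lists fixed before the data were examined were matched on its synonyms, which 246 genes had. Of 31 pathway lists 28 had a member and 7 had the 5 genes needed for a test: actin, arabinogalactan protein, auxin, calcium signalling, class III peroxidase, ethylene and NAC factor. The abscisic acid, heat shock protein and defence protein lists had 0 members, and so did the 4 lists of markers of other tissues (photosynthesis, seed storage, pollen and anther, xylem), so that neither could be measured. Lists were tested with camera in limma at a preset correlation of 0.01 against the genes with a synonym, adjusted over the lists of a contrast, then with an estimated correlation, and with fry. By fry 6, 6, 7 and 7 of the lists moved one way on balance at 0, 5, 10 and 20 dpa. Of the camera calls, those at 5 dpa hold with an estimated correlation and those at 0 and 10 dpa do not. Numbers of genes called in a list use the p-values adjusted over all probe sets. Adjusted over the list alone, the numbers were the same except for peroxidases at 0 dpa (7 in place of 6), arabinogalactan proteins at 5 dpa (9 in place of 8) and 10 dpa (11 in place of 10), expansins at 0 dpa (3 in place of 1), fibre initiation regulators at 0 dpa (2 in place of 1), and at 20 dpa xyloglucan endotransglucosylases (3 in place of 2) and late embryogenesis abundant genes (2 in place of 1). The camera direction was Up where the mean was negative for arabinogalactan proteins at 0 dpa and calcium signalling at 10 dpa, and at 5 dpa calcium signalling had a negative median beside a positive mean.

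The rule for named genes was set before the data were examined: among called probe sets with 1 gene and an informative name whose drought and control values do not overlap, the 8 largest rises and 8 largest falls per stage and the 5 and 5 largest per difference of stages, then the 2 members with the smallest p of each list called. Other list members named as examples of their list, and the genes named for the mean over stages, were chosen after their values were seen.

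The tests were tried on simulated data with the spread of these arrays. Of 50 probe sets changed by 1 on the log2 scale, limma called 98%, 96%, 94% and 98% at 0, 5, 10 and 20 dpa, and of those changed by 0.25 it called 16%, 24%, 22% and 18%. Between 5 and 11 of the unchanged probe sets were called at a stage. Only 50 probe sets were changed at each size, whereas 44.2% to 60.3% of probe sets were called at the real stages. The adjustment of p is therefore stricter in the simulations, and these shares do not carry over to the real data. In 100 simulations with no list changed, camera called a list in 5, and it called a list raised by 1 in 100 of 100. The simulated genes varied independently and the genes outside the raised list were unchanged, whereas many genes changed in the real data. These rates therefore do not carry over, and a list not called by camera is not shown to lack a common direction. At 10 dpa the 12 arabinogalactan protein genes, with a mean of −1.29, had a camera adjusted p of 0.300.

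Alternatives to the settings were quantile normalization of the deposited values (which acts on centred values), centring of each array on its median, array weights, a trended and robust variance, fits to the arrays of a contrast alone, probe sets of G. hirsutum design only, a minimum of 2-fold, replicate number as a block, each array left out in turn, and for lists an estimated correlation, ranks and all probe sets of a gene. Chosen after the data had been seen were scaling on the poly-A spike controls (the mean of 12 probe sets of dap, lys, phe and thr subtracted from each array), the 5′ minus 3′ signal of 3 control transcripts (actin, ss1 and ubq11) as a covariate, and all probe sets as the background of camera.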

Results

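Transcript levels were measured with the Affymetrix cotton GeneChip in field-grown Gossypium hirsutum cv. Bikaneri Nerma, an upland cotton cultivar. The 24 arrays formed 8 groups of 3 biological replicates: control and drought plants at 0, 5, 10 and 20 days post anthesis (dpa, days after the flower opened). RNA came from bolls, the young fruits, at 0 and 5 dpa and from ovules bearing fibre, the long hairs of the seed coat, at 10 and 20 dpa. For 0 dpa the note on collection also names leaf, while the note on extraction names bolls. In the drought plots irrigation was stopped at peak flowering, and a shelter kept out rain. The values were log2 signals already centred for each probe set on the median of the 6 arrays of its stage. They therefore give the difference between drought and control within a stage, but neither the level of a transcript nor its change between stages in control plants. An array has no count depth, so the number of arrays limits the precision. The standard deviation of the difference between 2 replicate arrays ran from 0.14 to 0.29 on the log2 scale, and the median standard error of a difference between drought and control was 0.10.

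Of the 23973 probe sets tested, 697 carried 1 gene in the annotation, and 242 genes had a name that tells something of their product. The genes named here come from that part of the array, and 23230 probe sets had no gene at all. Genes are given with their identifier in the assembly Gossypium_hirsutum_v2.1. Each value is the log2 difference, drought minus control, with its standard error (SE) from the limma fit and n = 3 arrays per group. All adjusted p-values are from limma or its gene set test camera.

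At 0 dpa the comparison asks how bolls of drought plants differed from bolls of control plants on the day of flowering. G9, a gene for a polygalacturonase, which splits pectin in cell walls (LOC107942091, chromosome A04, 1935312 to 1936899), was 248-fold higher in drought, with a log2 difference of 7.95 ± 0.08 (SE, n = 3 per group). The sucrose synthase gene SusA1 (LOC107910106) rose by 1.94 ± 0.38 (0.17, without passing the test, with a covariate for RNA integrity), the kinesin gene KCH1 (LOC107927185) by 1.72 ± 0.14, and the ethylene synthesis gene ACS3/ACS6 (LOC107947061), which codes for 1-aminocyclopropane-1-carboxylate (ACC) synthase, by 1.23 ± 0.06. Class III peroxidases, secreted enzymes that act on phenolic compounds and cell walls, were lower. Of the 8 listed peroxidase genes 6 fell and 2 did not pass the test (camera adjusted p = 0.0240, but adjusted p = 0.0530 with an estimated correlation and 0.0522 on ranks).

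Among these peroxidases pod7 (LOC107936187) was 11.2-fold lower, at −3.48 ± 0.08, and pod10 (LOC107914313) stood at −2.09 ± 0.10. The other large falls were those of the zinc finger gene ZFP1 (LOC107933034) at −2.34 ± 0.08, POX5 (LOC107914564) at −1.90 ± 0.08, SCP (LOC107904219) at −1.08 ± 0.23, cdn1 (LOC107903500), whose cadinene synthase starts the path to gossypol, at −1.01 ± 0.15, POX10 (LOC107937645) at −0.99 ± 0.11 and the transcription factor gene NAC7 (LOC107909534) at −0.96 ± 0.07. The other large rises were those of DBP3b (LOC107890730) at 1.68 ± 0.08, AOX1 (LOC107939301) at 1.61 ± 0.11, MFP (LOC107932835) at 1.41 ± 0.17 and the transcription factor gene WRKY24/WRKY71 (LOC107906829) at 1.31 ± 0.08. POX5 and POX10 did not match the fixed list of peroxidases, although their names resemble those of peroxidase genes. Counts and tests for that list leave them out at every stage. The highest adjusted p among the 16 genes named at this stage was 0.000849. The other tested lists were not called by camera: 3 of 5 actin genes fell, 2 of 9 ethylene genes rose and 5 fell, 2 of 5 auxin genes rose (1 of them, ARF1, turned to −0.06 when arrays were scaled on the spike controls), 1 of 5 calcium signalling genes rose, 1 of 6 NAC genes fell, and 1 of 12 arabinogalactan protein genes rose while 2 fell (adjusted p from 0.514 to 0.962). Of these lists fry left only that of the arabinogalactan protein genes uncalled (adjusted p = 0.326).

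By limma, 10606 of the 23973 probe sets (44.2%) differed at 0 dpa, 5123 of them higher and 5483 lower in drought. A change of at least 2-fold was found at 570 higher and 307 lower probe sets, or at 376 higher and 511 lower ones with scaling on the spike controls. The 3 drought and 3 control values did not overlap at 56.6% of probe sets, where chance gives 10%. The 5′ minus 3′ signal of control transcripts, taken here as a sign of RNA integrity, was 0.93 higher in drought arrays. These are transcripts of cotton itself, so the signal may also carry a change in their expression. With that signal as a covariate 5400 probe sets were called, and SCP stood at −0.71 without passing the test. The effects of the probe sets changed at least 2-fold kept a slope of 0.934 on their former size and 781 of the 877 were still called, while the median standard error rose from 0.13 to 0.17. With scaling on the spike controls 6246 probe sets were called, 24.1% of them higher.

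**Figure D1:**
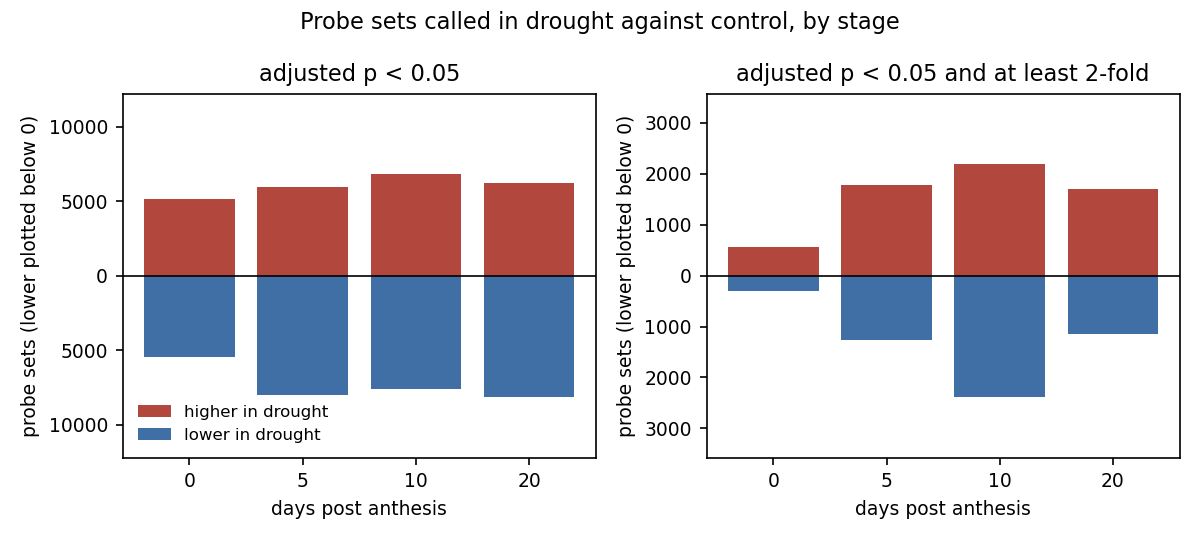
Number of probe sets called in drought against control (y axis, probe sets, with higher ones above and lower ones below 0) at each stage in days post anthesis (x axis). The left panel counts all calls at an adjusted p under 0.05 and the right panel those of at least 2-fold, which number 877 at 0 dpa and 4574 at 10 dpa; with arrays scaled on the spike controls, 5.09% of the calls at 10 dpa and 4.48% of those at 20 dpa are higher.

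At 5 dpa the same comparison was made in bolls with growing ovules and young fibre. Genes for NAC transcription factors, a family with known regulators of senescence and stress responses, rose together: 4 of the 6 listed genes rose and 2 did not pass (camera adjusted p = 0.0139, and adjusted p = 0.0311 with an estimated correlation). NAC5/NAC8 (LOC107892421, chromosome A11, 101177311 to 101178925) was 26.6-fold higher, at 4.73 ± 0.18 (SE, n = 3 per group), NAC4 (LOC107916546) stood at 4.10 ± 0.17, NAC7 at 2.70 ± 0.07 and NAC2 (LOC107962533) at 2.65 ± 0.08. Ethylene genes also rose as a group, with 7 of 9 genes higher and 1 lower (camera adjusted p = 0.0139, and adjusted p = 0.0311 with an estimated correlation). ACS3/ACS6 rose by 3.01 ± 0.06, and ACO3 (LOC107915412), an ACC oxidase gene for the last step of ethylene synthesis, by 1.62 ± 0.05, while 1 of the 2 genes named ACO1 (LOC107954048) stood at −1.26 ± 0.12.

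ZFP1 was 21.7-fold higher at 5 dpa (4.44 ± 0.08), and the transcription factor genes RAV1 (LOC107946446), MYB5 (LOC107912305) and MYB (LOC107909337) rose by 4.25 ± 0.25, 3.09 ± 0.13 and 2.75 ± 0.10. The late embryogenesis abundant genes Lea5-D (LOC107916177) and Lea14-A (LOC107922715), of a class known from drying seeds, rose by 2.57 ± 0.06 and 1.90 ± 0.07. The largest fall was that of RCA1 (LOC107942112), which codes for Rubisco activase, an activator of carbon fixation, at −3.46 ± 0.13. It was followed by AOX1 at −2.95 ± 0.11, GHMYB10 (LOC107951064) at −2.15 ± 0.08, POX10 at −2.15 ± 0.11, the cyclopropane fatty acid synthase gene CPA-FAS-1 (LOC107933118) at −2.05 ± 0.18, the sucrose synthase gene susC (LOC107901030) at −2.00 ± 0.05, the fibre gene myb109 (LOC107961466) at −1.87 ± 0.10, and FLA19 (LOC107954983), a fasciclin-like arabinogalactan protein gene, at −1.84 ± 0.11. The highest adjusted p among the 18 named genes was 4.77e-09.

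At 5 dpa all 4 listed expansins, proteins that loosen cell walls, fell, as did all 4 tubulins and all 5 actin genes, with EXPA3D (LOC107904848) at −1.63 ± 0.10, BTub4 (LOC107936697) at −1.48 ± 0.06 and ACT7 (LOC107959435) at −0.69 ± 0.06. Of the 12 arabinogalactan protein genes 7 fell and 1, FLA4 (LOC107946184), rose by 1.19 ± 0.06. The lists of actin and arabinogalactan protein genes were not called by camera, which compares a list with other genes (adjusted p = 0.208 for each, 0.0318, lower, against all probe sets as background, but 0.183 and 0.0598 on that background with an estimated correlation). By fry, which makes no such comparison, both moved one way on balance (adjusted p = 9.86e-10 and 1.27e-13). The lists of expansin and tubulin genes were too small to test. Of the 8 peroxidase genes 4 rose and 2 fell, of the 5 auxin genes 3 rose and 1 fell, and of the 5 calcium signalling genes 1 rose and 3 fell, although both annexins among these (AnnGh1, LOC107905123, and Anx1, LOC107913673) turned to 0.10 and 0.07 with scaling on the spike controls. The adjusted p of these 3 lists ran from 0.290 to 0.907.

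By limma, 13963 probe sets (58.2%) differed at 5 dpa, 5947 higher and 8016 lower, and the groups did not overlap at 67.3%. At least 2-fold changes were 1790 higher and 1258 lower, or 2492 higher and 615 lower with scaling on the spike controls. The 5′ minus 3′ signal of control transcripts was 0.54 higher in drought arrays and the spike controls were lower, at −0.25. With arrays scaled on those controls, 70.1% of the calls were higher in drought, where 42.6% were without.

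At 10 dpa, in ovules with elongating fibre, NAC genes were again higher in drought. NAC5/NAC8 was 209-fold higher (7.71 ± 0.18, SE, n = 3 per group), NAC4 stood at 5.89 ± 0.17, NAC2 at 4.32 ± 0.08 and NAC7 at 4.25 ± 0.07. As at 5 dpa, 4 of the 6 NAC genes rose and 2 did not pass (camera adjusted p = 0.0244, and adjusted p = 0.0568 with an estimated correlation). ZFP1 rose 125-fold (6.97 ± 0.08), pod10 by 5.88 ± 0.10, GEPH (LOC107918357) by 5.09 ± 0.09, RAV1 by 4.67 ± 0.25, Lea5-D by 4.64 ± 0.06, MYB by 4.58 ± 0.10 and the lipoxygenase gene Lox1 (LOC107919998) by 4.34 ± 0.05. The largest falls among named genes were those of FLA13 (LOC107911922) at −4.38 ± 0.08, the expansin gene EXPA11A (LOC107885990), 15.9-fold lower, the beta-tubulin gene BTub1 (LOC107962977) at −3.52 ± 0.13, the sterol methyltransferase gene SMT2-2 (LOC107905551) at −3.40 ± 0.15 and the cellulose synthase gene CesA1 (LOC107909647) at −3.06 ± 0.11.

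All 4 expansin genes, all 4 listed tubulin genes and all 4 flavonoid genes fell at 10 dpa, among them EXPA3D at −2.93 ± 0.10, BTub4 at −1.06 ± 0.06, the chalcone synthase gene CHS3 (LOC107912380) at −1.77 ± 0.05 and the dihydroflavonol reductase gene DFR (LOC107957957) at −2.25 ± 0.06. Of the 12 arabinogalactan protein genes 8 fell, with FLA12 (LOC107945624) at −2.90 ± 0.06 and FLA15 (LOC107896273) at −2.51 ± 0.06, and 2 rose, FLA6 (LOC107898811) and FLA4, which turned negative with scaling on the spike controls (camera adjusted p = 0.300, and 0.0206, lower, against all probe sets as background, or 0.0490 there with an estimated correlation). SMT2-1 (LOC107959396), a second sterol methyltransferase gene, fell to −3.04 ± 0.05, and CPA-FAS-2 (LOC107936133) to −3.02 ± 0.07. The highest adjusted p among the 18 named genes was 9.13e-13. Of the 9 ethylene genes 5 rose and 2 fell (camera adjusted p = 0.0928), and of those that rose ACS3/ACS6 turned to −0.67 with scaling on the spike controls. As that scaling shifts every difference at this stage by −1.28, ACO3 (1.48) also loses most of its rise. The rises of ERF7 (LOC107941184, 2.13), ERF8 (LOC107922990, 3.47) and ACO1 (LOC107905899, 4.21) are larger than the shift. Of the 8 peroxidase genes 3 rose and 3 fell (adjusted p = 0.406), and of those that rose pod1 (LOC107945392) turned to −0.08 with that scaling. Of the 5 actin genes 3 fell (adjusted p = 0.326). Of the 5 auxin genes 2 rose and 3 fell and of the 5 calcium signalling genes 1 rose and 2 fell (adjusted p = 0.786 for each), but those that rose, Aux4 (LOC107923964), Aux2 (LOC107941658) and CBL2 (LOC107922500), turned negative with that scaling.

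By limma, 14445 probe sets (60.3%) differed at 10 dpa, 6831 higher and 7614 lower, and the groups did not overlap at 62.8%. At least 2-fold changes were 2188 higher and 2386 lower, or 684 higher and 17680 lower with scaling on the spike controls. The poly-A spike controls, bacterial transcripts added to the RNA, were 1.28 higher in drought arrays, and the 5′ minus 3′ signal of control transcripts was 0.59 higher, or 0.27 without drought replicate 2, the array with the widest scatter at this stage. With arrays scaled on the spike controls 22785 probe sets were called and 5.09% of them were higher, so that the direction of a moderate change at this stage depends on the scale. Without drought replicate 2 the count was 14038.

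At 20 dpa, in ovules with fibre laying down secondary wall, WRKY24/WRKY71 was 16.2-fold higher in drought (4.02 ± 0.08, SE, n = 3 per group) and ACS3/ACS6 13.8-fold (3.79 ± 0.06), while ACO3 was 10.9-fold lower (−3.45 ± 0.05). POX5 fell to −3.58 ± 0.08 and Lox1 to −2.83 ± 0.05. KCS12 (LOC107928969), a ketoacyl-CoA synthase gene of very-long-chain fatty acid synthesis, stood at −3.28 ± 0.13, and DFR at −2.89 ± 0.06. Further rises were those of DBP3b at 3.65 ± 0.08, SusA1 at 3.12 ± 0.38 (−0.97, without passing the test, with the 5′ minus 3′ signal as a covariate), MFP at 2.79 ± 0.17, GRPL1 (LOC107953490) at 2.79 ± 0.14, ASP3 (LOC107901245) at 2.66 ± 0.17 and BC1 (LOC107910621) at 2.47 ± 0.17, and further falls those of GHMYB10 at −2.74 ± 0.08, CMDR1 (LOC107942025) at −2.66 ± 0.09 and the auxin gene Aux6 (LOC107928986) at −2.38 ± 0.12.

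At this stage camera called 0 of the 7 tested lists, 1 list had an unadjusted p under 0.05, and fry, which tests whether the genes of a list move one way on balance without reference to other genes, called 7. The list with the lowest p was that of the peroxidases, of which 7 of 8 fell (adjusted p = 0.238, and 0.00860 against all probe sets as background, or 0.0289 there with an estimated correlation), with pod7 at −2.15 ± 0.08 and pod10 at −1.23 ± 0.10 (−0.72, without passing the test, with the 5′ minus 3′ signal as a covariate). Of the 9 ethylene genes 3 rose and 6 fell, of the 6 NAC genes 3 rose and 2 fell, of the 12 arabinogalactan protein genes 4 rose and 2 fell, of the 5 auxin genes 4 fell, of the 5 actin genes 3 fell and of the 5 calcium signalling genes 2 rose and 2 fell (adjusted p from 0.475 to 0.573). With scaling on the spike controls ERF3 (LOC107926309), NAC7, FLA6, FLA7 (LOC107942443), FLA15, CBL1 (LOC107912199) and Anx1, which are among the rises, turned negative. That scaling shifts every difference at this stage by −1.11, so the rises of NAC4 (1.23), ERF9 (LOC107932376, 1.25) and FLA11 (LOC107922285, 1.26) come close to 0 with it. Those of ACS3/ACS6 (3.79) and NAC2 (1.72) are larger than the shift. Of the 4 expansin genes 3 fell, with EXP1 (LOC107914543) at −1.99 ± 0.06, and 3 of 4 listed tubulin genes rose by at most 0.31 ± 0.05, although the 3 tubulins and the expansin that rose, EXPA11A, turned negative with scaling on the spike controls. The listed BTub4 fell to −0.84. BTub1, a beta-tubulin gene that is not on the list, fell to −1.22 (−0.75, without passing the test, with the 5′ minus 3′ signal as a covariate).

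By limma, 14380 probe sets (60.0%) differed at 20 dpa, 6231 higher and 8149 lower, and the groups did not overlap at 62.7%. At least 2-fold changes were 1693 higher and 1146 lower, or 456 higher and 15894 lower with scaling on the spike controls, and the highest adjusted p among the 16 named genes was 4.48e-07. The 5′ minus 3′ signal of control transcripts was 2.16 higher in drought arrays and the spike controls were 1.11 higher. With the 5′ minus 3′ signal as a covariate 4940 probe sets were called. The effects of the probe sets changed at least 2-fold kept a slope of 0.745 on their former size, and the median standard error rose from 0.11 to 0.25. With scaling on the spike controls 22607 were called, 4.48% of them higher.

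**Figure D2:**
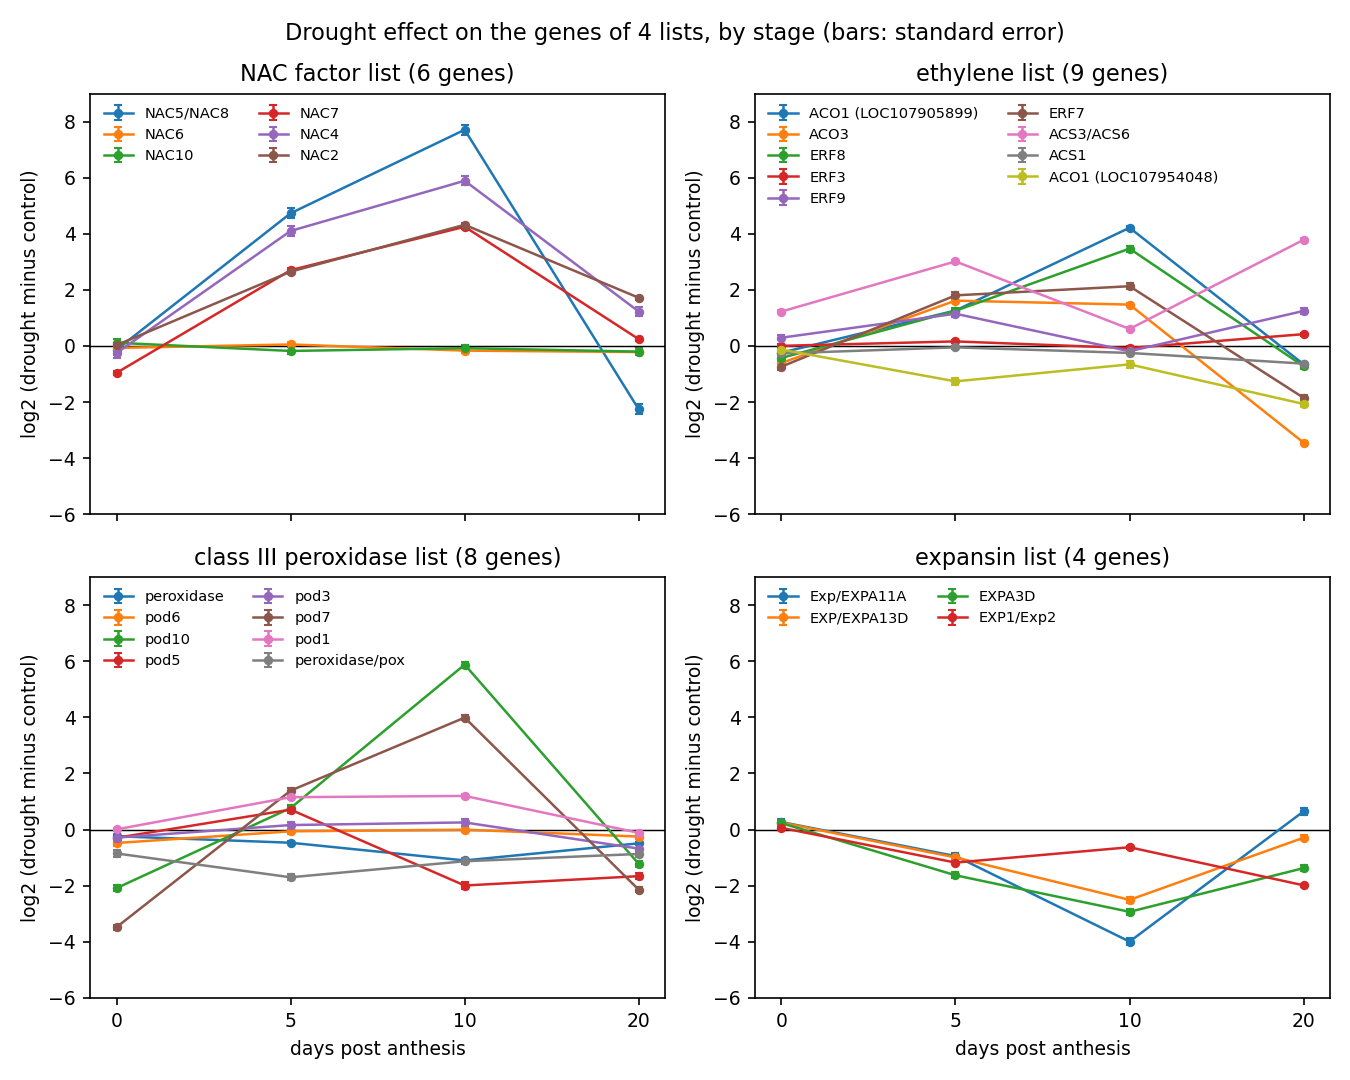
Log2 difference, drought minus control (y axis), of each gene of 4 lists at each stage in days post anthesis (x axis); points are limma estimates from 3 arrays per group, bars are standard errors, and lines join the stages of a gene. NAC5/NAC8 runs from −0.13 at 0 dpa to 7.71 at 10 dpa and −2.26 at 20 dpa, and the expansin EXPA13D from 0.25 to −2.51 and −0.29, while ACS3/ACS6 at 10 dpa turns from 0.61 to −0.67 and EXPA11A at 20 dpa from 0.65 to −0.46 with arrays scaled on the spike controls.

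Differences of the drought effect between consecutive stages were tested in the same model. From 0 to 5 dpa, ZFP1 changed from −2.34 to 4.44, a difference of 6.78 ± 0.12 (SE, n = 3 per group), pod7 from −3.48 to 1.39, a difference of 4.87 ± 0.12, and POX5 by 4.26 ± 0.11. NAC5/NAC8 and NAC4 differed by 4.87 ± 0.25 and 4.35 ± 0.24. The opposite difference was found for G9, at −8.07 ± 0.11, which stood at −0.11 at 5 dpa, for AOX1 at −4.56 ± 0.15, RCA1 at −3.83 ± 0.19, GHMYB10 at −2.39 ± 0.11 and PAP1 (LOC107905479) at −1.90 ± 0.22. Between 5 and 10 dpa the tissue changed too, from bolls to ovules bearing fibre, so stage and tissue cannot be told apart in these differences. RCA1 and AOX1 stood at −3.46 and −2.95 at 5 dpa. The drought effect was higher at 10 than at 5 dpa for pod10 by 5.11 ± 0.15, RCA1 by 3.17 ± 0.19, NAC5/NAC8 by 2.98 ± 0.25, ACO1 (LOC107905899) by 2.95 ± 0.09 and AOX1 by 2.85 ± 0.15. It was lower at 10 than at 5 dpa for EXPA11A at −3.05 ± 0.16, pod5 (LOC107922335) at −2.70 ± 0.17, FLA13 at −2.66 ± 0.11, CesA1 at −2.51 ± 0.15 and ACS3/ACS6 at −2.41 ± 0.09.

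From 10 to 20 dpa NAC5/NAC8 turned from 7.71 to −2.26, a difference of −9.97 ± 0.25 (SE, n = 3 per group). Lox1 differed by −7.16 ± 0.07, pod10 by −7.11 ± 0.15, GEPH by −7.04 ± 0.13 and pod7 by −6.14 ± 0.12. SMT2-2 turned from −3.40 to 1.98 (0.55, without passing the test, with the 5′ minus 3′ signal as a covariate), a difference of 5.38 ± 0.21, and GRPL1, EXPA11A, FLA13 and ASP3 differed by 4.92 ± 0.20, 4.64 ± 0.16, 4.40 ± 0.11 and 3.92 ± 0.24. The drought effect differed at 12768 probe sets between 0 and 5 dpa, at 11160 between 5 and 10 dpa and at 14366 between 10 and 20 dpa, of which 3331, 2952 and 5842 differed by at least 2-fold. The highest adjusted p among the 10 genes named for each difference was 4.27e-07, 3.53e-09 and 6.93e-12. With scaling on the spike controls 23159 probe sets differed between 5 and 10 dpa, 1.72% of them upward.

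A mean over the 4 stages gives the average drought effect. A large change at a single stage can move it too, so a call for the mean does not show a change shared over development. The late embryogenesis abundant gene Lea14-A rose at each stage, by 0.89 ± 0.07, 1.90 ± 0.07, 3.29 ± 0.07 and 1.17 ± 0.07 (SE, n = 3 per group), although with scaling on the spike controls it stood at 0.06 at 20 dpa, without passing the test. SusA1 rose at each stage too, but with that scaling it stood at 0.07 at 10 dpa, without passing the test, and with the 5′ minus 3′ signal as a covariate it passed at 5 dpa alone. FLA19, at −0.71, −1.84, −1.95 and −1.38, BTub1, and DET2 (LOC107948867), a steroid reductase gene of brassinosteroid synthesis, at −0.36, −1.21, −0.87 and −1.11, fell at each stage, but with that covariate BTub1 did not pass at 0 and 20 dpa, nor DET2 at 0 dpa. The mean differed from 0 at 16423 probe sets (68.5%), 7567 higher and 8856 lower, of which 1020 and 623 were at least 2-fold. In all 4 stages 48 probe sets were at least 2-fold higher and 8 at least 2-fold lower, of 7164 that changed at least 2-fold at any stage. At 721 probe sets at least 2-fold changes of opposite direction were found at different stages. With the 5′ minus 3′ signal as a covariate the mean differed at 9090 probe sets. With scaling on the spike controls it differed at 22224, 7.50% of them higher, where 46.1% were without.

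The stages with most in common were 5 and 10 dpa, and 0 and 20 dpa. Of the probe sets changed at least 2-fold, 1116 were higher at both 5 and 10 dpa, where 163 were expected if the stages were independent, and 753 were lower at both, where 125 were expected. At 0 and 20 dpa 313 were higher at both against 40.3 expected (one-sided Fisher's exact test, p = 2.65e-211) and 136 lower at both against 14.7 expected (Fisher's exact test, p = 9.02e-97). Changes of opposite direction were also more frequent than expected in places, with 145 probe sets lower at 0 and higher at 10 dpa against 28.0 expected, and 313 higher at 10 and lower at 20 dpa against 105. The stages share no arrays, but probe sets are not independent replicates, so these probabilities are too small. Across all probe sets the Pearson correlation of the drought effects was 0.66 for 5 and 10 dpa, 0.44 for 0 and 20 dpa, 0.25 for 5 and 20 dpa, 0.14 for 0 and 5 dpa, 0.03 for 10 and 20 dpa and −0.04 for 0 and 10 dpa.

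The control transcripts on the arrays differed between the groups too. The 5′ minus 3′ signal, a mean over actin, ss1 and ubq11, was higher in each drought array than in each control array of the same stage, by 0.93, 0.54, 0.59 and 2.16 at 0, 5, 10 and 20 dpa (exact permutation test, two-sided, p = 0.1 at each stage, the smallest p that 3 against 3 arrays can give). The poly-A spike controls also separated the groups at each stage, with differences of 0.20, −0.25, 1.28 and 1.11 (exact permutation p = 0.1 at each stage). The hybridisation controls, added after labelling, differed by 0.02, 0.07, 0.35 and −0.33, and separated the groups at 10 dpa but not at the other stages. Of the control transcripts, actin did not separate the groups in its 5′ minus 3′ signal at 10 dpa, nor ss1 at 5 dpa. Their 3′ signals differed too at 10 dpa, by −0.76 (actin), −1.07 (ss1) and 1.12 (ubq11), and at 20 dpa by −0.42, 0.08 and 0.03. Integrity and a response of these transcripts to drought therefore cannot be told apart in the 5′ minus 3′ signal.

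**Figure D3:**
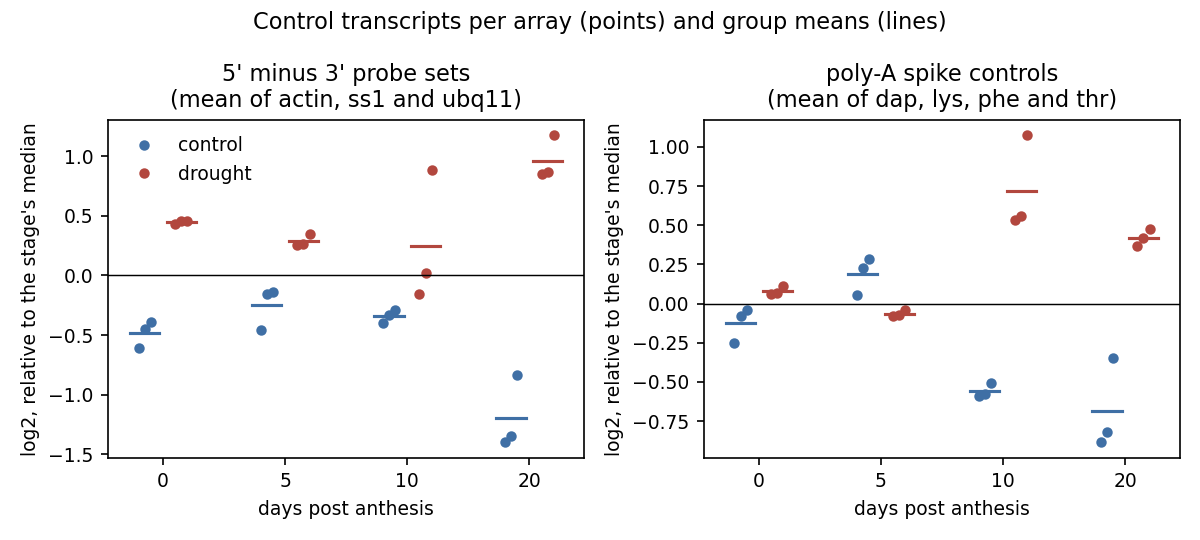
Mean log2 signal of control probe sets per array (y axis, relative to the median of the 6 arrays of a stage) at each stage in days post anthesis (x axis), with control arrays in blue, drought arrays in red and lines at the means of 3 arrays. The left panel shows the 5′ minus 3′ signal, whose means lie 2.16 apart at 20 dpa, and the right panel the poly-A spike controls, whose means lie 1.28 apart at 10 dpa.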

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

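Of the tests below, scaling on the spike controls, the 5′ minus 3′ covariate and the test on fibre genes were chosen after the results were seen. A result is listed here where the drought effect differed between stages by a test of that difference, or where a signal lay outside the gene measurements, in control probe sets, and separated the drought from the control arrays by at least 0.5 on the log2 scale, a minimum chosen after these controls had been seen. With groups of 3 arrays no test for a single deviating array was applied.

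The drought effect differed between 0 and 5 dpa at 12768 probe sets, between 5 and 10 dpa at 11160 and between 10 and 20 dpa at 14366. Between 5 and 10 dpa the tissue changed too, from bolls to ovules bearing fibre, so stage and tissue cannot be told apart there. Named genes called in opposite directions at consecutive stages differed from 0 to 5 dpa by 6.78 (ZFP1), 4.87 (pod7), 4.26 (POX5), −4.56 (AOX1), −3.83 (RCA1), −2.39 (GHMYB10) and −1.90 (PAP1). From 5 to 10 dpa pod5 differed by −2.70. From 10 to 20 dpa the differences were 5.38 (SMT2-2), 4.92 (GRPL1), 4.64 (EXPA11A), 3.92 (ASP3), −9.97 (NAC5/NAC8), −7.16 (Lox1), −7.11 (pod10), −7.04 (GEPH) and −6.14 (pod7). Under scaling on the spike controls EXPA11A was lower at both stages, at −0.46 at 20 dpa, and RCA1 and GHMYB10 at 0 dpa, at 0.16 and 0.04, did not pass. With the covariate GHMYB10 (0.19) and PAP1 (0.13) at 0 dpa and SMT2-2 (0.55), EXPA11A (−0.15) and pod10 (−0.72) at 20 dpa did not pass.

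In the control probe sets the 5′ minus 3′ signal was higher in drought arrays by 0.93, 0.54, 0.59 and 2.16 at 0, 5, 10 and 20 dpa, and the poly-A spike controls by 1.28 at 10 dpa and 1.11 at 20 dpa. Without drought 10 dpa replicate 2, whose signals stand apart, the differences at 10 dpa were 0.27 and 1.10, and without control 20 dpa replicate 1 those at 20 dpa were 2.34 and 1.27. The ribosomal RNA probe set GhirRNA.1 differed by −0.56 at 5 dpa and −1.32 at 10 dpa, GhirRNA.2 by 1.49, 0.67 and 1.60 at 5, 10 and 20 dpa, GhirRNA.3 by −0.95 at 20 dpa and GhirRNA.4 by −0.51 at 5 dpa.

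At 20 dpa 2839 probe sets changed at least 2-fold, at the stage where the 5′ minus 3′ signal differed most. Loss of RNA integrity in the control arrays could account for part of this: control replicate 1, whose signal lay 0.54 above the other control arrays, deviated from them in the direction of the drought effect at 71.3% of these probe sets, and that slope, scaled to the difference of 2.16 between the groups, accounts for a share of 0.352 of the effect. With the signal as a covariate over all arrays the effect kept a slope of 0.745 on its former size (0.725 to 0.782 with 1 array left out), and 1528 probe sets were still called at 2-fold, while the median standard error rose from 0.11 to 0.25. Neither value decides, so integrity and drought cannot be told apart for part of these probe sets at 20 dpa, where, as at the other stages, the groups share no value of the signal. The correlation between the effects at 0 and 20 dpa was 0.44, and with the covariate r was 0.364 (0.358 to 0.437 with 1 array left out). This does not decide whether integrity is its whole cause. A covariate measured with error removes too little. Both adjusted effects also have the same fitted slope taken out, so an error in that slope itself adds to their correlation. A drought effect common to both stages stays open as untested.

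At 10 dpa the large rises and falls have 3 candidate explanations besides drought. Integrity as a shared slope is argued against, since with the covariate the effect of the 4574 probe sets changed at least 2-fold kept a slope of 0.989 (0.983 to 1.00 with 1 array left out) and 4220 were still called at 2-fold. A covariate measured with error removes too little here as well, and the groups share no value of the signal at 10 dpa either. A shift of scale, shown by the spike controls at 1.28, cannot be told apart from a difference in the amount of spike added per RNA, which is unknown, and the 31.3% of probe sets higher by at least 2-fold that stayed so under scaling on them decides nothing, as the shift itself fixes that share. A smaller share of fibre cells in the drought ovules was examined in 8 genes known from fibre (E6, FSLTP2, ACT1, BTub1, EXP1, Rac13, AnnGh1, CTL1). They would fall alike only if each were expressed in fibre alone at a fixed level, which was not tested. They spread over 4.69, a range that no scaling of arrays changes. BTub1 (−3.52) and CTL1 (1.18, or −0.10 with scaling on the spike controls) alone carry it, and BTub1 is among the falls to be explained, so the range cannot decide. For the other 6 genes, which lie from −0.63 to −0.00 (a range of 0.63, 3 of them not lower) or from −1.91 to −1.28 under scaling on the spike controls (0 not lower), a smaller share cannot be told apart from no change, since the scale decides.

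At 0 dpa 45 probe sets were at least 8-fold higher in drought bolls, G9 among them at 7.95. G9 is known from pollen, so pollen RNA in the drought bolls may have raised them, as bolls at flowering can carry anthers or pollen. In that case few of them would be higher at later stages, and 10 of the 45, or 22.2%, were also at least 2-fold higher at 5, 10 or 20 dpa, with G9 at −0.11 at 5 dpa. That share lies between the values set beforehand for and against pollen. Those values take no account of the share over all probe sets. Of the 23973 probe sets, 1790, 2188 and 1693 were at least 2-fold higher at 5, 10 and 20 dpa, so the test cannot decide. The pollen list had 0 measured members, so pollen cannot be told apart from a drought effect on the boll. Whether anthers were removed is not given in the labels.

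Other splits of the same arrays into groups were fitted in the same way. At each stage the 10 possible splits are too few for a share under 0.05; the real split called 10606, 13963, 14445 and 14380 probe sets at 0, 5, 10 and 20 dpa, as the 1 highest of 10 each time, and the highest other split called 0, 0, 2 and 5. For the mean over stages 1 of 100 splits, the real one, called as many as 16423 (highest other 12687), so splits drawn at random seldom call as many. The spike controls and the 5′ minus 3′ signal separate the same groups at each stage. These splits therefore cannot tell drought from another difference between the groups. For the differences as many were called by 2 of 100 splits between 0 and 5 dpa (real 12768, highest other 13623), 1 of 100 between 5 and 10 dpa (11160 against 11053) and 1 of 100 between 10 and 20 dpa (14366 against 10170). These splits test for no drought effect at either stage rather than for equal effects, so their shares say nothing about whether the effect differed between stages. The split that called 13623 keeps drought and control arrays apart at both stages with 1 stage turned round, and those highest for the mean and the other differences keep at least 1 stage whole, which points to the strong grouping of arrays within each stage. Splits that mix drought and control at every stage called at most 0, 0, 0 and 1.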

How the results depend on the processing

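Scaling on the spike controls, the 5′ minus 3′ covariate and all probe sets as the background of camera were tried after the results were seen; the cause of a change was not tested unless the setting itself gives it. For the counts of probe sets, lists and overlaps, 14 results under these added settings and 186 under planned settings stayed within 1.5 times, those of planned settings including quantile normalization, array medians, array weights, a trended variance, fits to the arrays compared and G. hirsutum probe sets. Of 98 results for the named genes with the largest changes, 98 kept direction and call under each scaling and under the replicate block, and 768 of 768 with 1 array left out. With the covariate SusA1 at 20 dpa turned to −0.97, and SusA1 and SCP at 0 dpa stood at 0.17 and −0.71, no longer called. POX10 and NAC7 at 0 dpa lie under 2-fold.

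With spike scaling 6246 probe sets were called at 0 dpa, 22785 at 10 dpa, 22607 at 20 dpa, 22224 for the mean and 23159 between 5 and 10 dpa. It moved the median of all probe sets by −0.20, 0.25, −1.28 and −1.11 at 0, 5, 10 and 20 dpa, and the share of calls that were higher from 48.3% to 24.1%, from 42.6% to 70.1%, from 47.3% to 5.09% and from 43.3% to 4.48%. For the mean that share moved from 46.1% to 7.50%, and for the differences from 41.7% to 84.6%, 50.3% to 1.72% and 50.6% to 64.3%. At least 2-fold changes under it were 376 higher and 511 lower at 0 dpa, 2492 and 615 at 5 dpa, 684 and 17680 at 10 dpa and 456 and 15894 at 20 dpa. It turned 1, 3, 13 and 18 called list genes; the other scalings turned 0. With the gap covariate 5400 were called at 0 dpa, 4940 at 20 dpa and 9090 for the mean. At 0 dpa effects of probe sets changed at least 2-fold kept a slope of 0.934 on their former size, 781 of 877 stayed called, and the median standard error rose from 0.13 to 0.17. At 20 dpa both smaller effects (a slope of 0.745) and wider errors (0.11 to 0.25) came with it, and their parts in the lower counts were not separated.

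A minimum of 2-fold, which by construction calls fewer, left 877, 3048, 4574 and 2839 probe sets at the 4 stages, 1643 for the mean and 3331, 2952 and 5842 for the differences. The overlap of calls in the same direction became 262 for 0 and 5 dpa (4681 without the minimum), 132 for 0 and 10 (3781), 449 for 0 and 20 (6304), 1869 for 5 and 10 (9353), 739 for 5 and 20 (6177) and 639 for 10 and 20 dpa (5931).

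Of the lists called, 1, 2, 1 and 0 at the 4 stages, 0 remained at 0 dpa with an estimated correlation (adjusted p = 0.0530) and 0 with ranks (0.0522), and 0 at 10 dpa with an estimated correlation (0.0568). Over all alternatives the adjusted p ran from 0.000521 to 0.0530 for peroxidases at 0 dpa and from 0.000343 to 0.0568 for NAC genes at 10 dpa. With all probe sets as background 4 lists were called at 5 dpa, 2 at 10 dpa and 1 at 20 dpa. With an estimated correlation on that background 2 remained at 5 dpa, those of actin (0.183) and arabinogalactan protein genes (0.0598) being lost, and 2 and 1 at 10 and 20 dpa.

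With 1 array left out the counts ran from 9088 to 9867 at 0 dpa, 13181 to 13261 at 5 dpa, 13736 to 14038 at 10 dpa, 13277 to 14112 at 20 dpa, 16106 to 16446 for the mean, and 12058 to 12357, 10471 to 11465 and 13811 to 14456 for the differences, with 1, 2, 1 and 0 lists each time. With the replicate block 10571, 13960, 14437 and 14359 probe sets were called at the stages, 16408 for the mean and 12757, 11161 and 14343 for the differences, with overlaps of 4679, 3765, 6287, 9343, 6175 and 5919. Deviations of drought and control arrays of the same number correlated from −0.10 to 0.11, so the numbers do not pair them. A dim filter, a floor on low signals, the brightest probe set and the control stage contrasts were planned and not run, since the centred values hold no level; how far signals lay above background is therefore unknown. Changes of 0.25 were called for 16% to 24% of simulated probe sets, but few probe sets were changed there, so that share does not carry over to these data. A gene not called is still not shown to be unaffected.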

Other observations

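The genes here are members of lists too small for a test, so their values are given gene by gene and differences between stages were not tested for these groups. No test below was chosen after the result was seen except scaling on the spike controls. Ribosomal protein genes fell at 5 dpa in 4 of 4, with RPS16 (LOC107908898) at −1.24 ± 0.08 (SE, n = 3 per group), RPL44 (LOC107918511) at −1.03 ± 0.10 and RPS4 (LOC107938968) at −1.01 ± 0.06, and at 20 dpa 2 of 4 rose and 1 fell, where the 2 that rose turned negative with scaling on the spike controls. On the list labelled fibre initiation regulators, 2 of 2 genes, HOX3 (LOC107904747) and myb109, fell at 5, 10 and 20 dpa. The label is only the name of the list, and a role in initiation at these stages was not tested. The homeobox gene HOX3 stood at −1.15 ± 0.09 at 5 dpa and −0.63 ± 0.09 at 20 dpa. The aquaporin gene NIP6.1 (LOC107906429) fell to −1.28 ± 0.13, −1.89 ± 0.13 and −1.33 ± 0.13 at 5, 10 and 20 dpa. In very-long-chain fatty acid synthesis 3 of 4 genes fell at 5 and at 10 dpa, with FDH (LOC107893385) at −0.90 ± 0.07 and −1.40 ± 0.07.

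Of the sucrose synthase genes SusA1 rose at 0, 5 and 20 dpa in the fits without a covariate, and at 10 dpa by 1.35, or 0.07 without passing the test with scaling on the spike controls. The gene susC fell to −2.00 ± 0.05 at 5 dpa and −2.25 ± 0.05 at 20 dpa, with 0.26 ± 0.05 between them at 10 dpa, and Sus1 (LOC107958826) stood at −1.07 ± 0.04 at 10 dpa and 0.27 ± 0.04 at 20 dpa; susC at 10 dpa and Sus1 at 20 dpa turned negative with scaling on the spike controls. The gibberellin receptor gene GID1-2 (LOC107924318) rose by 2.07 ± 0.25, 2.94 ± 0.25 and 1.60 ± 0.25 at 5, 10 and 20 dpa. XTH3 (LOC107913353), of the xyloglucan endotransglucosylases that rejoin wall polysaccharides, stood at 1.48 ± 0.10, 3.84 ± 0.10 and −2.07 ± 0.10 at these stages, while the other 2 genes of its list fell at 5 and 10 dpa. WRKY15 (LOC107931629) stood at 0.68 ± 0.14, 2.76 ± 0.14 and −1.22 ± 0.14. The catalase gene CAT2 (LOC107943729) fell to −0.70 ± 0.08 at 5 dpa and −0.94 ± 0.08 at 20 dpa, and stood at 1.27 ± 0.08 at 10 dpa, or −0.01 with scaling on the spike controls.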
